A study of Mus musculus with 6 samples.

How the data were processed

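Poly-A RNA of the 889PF mouse cell line (129S1/SvImJ background) was prepared with an Illumina TruSeq kit and sequenced as paired reads of 100 bp, per the labels. The cells were grown in DMEM with 10% fetal bovine serum and 2 ug/mL puromycin, per the labels' protocols. TopHat, Cufflinks and Cuffdiff were used with genome build mm10, per the submitters' processing notes, which give no versions. The notes do not say which of these tools made which value.

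The authors deposited a single table of 10721 rows with RefSeq transcript identifiers and gene symbols. Per the file headers it holds, for each of replicates A and B, an FPKM of the control hairpin, an FPKM of Cd109 hairpins 1 and 2 together, a log2 fold change, a p-value and a q-value. FPKM, computed by the authors, is a fragment count scaled to transcript length and library size. The deposited log2 fold change is the log2 ratio of the knockdown over the control FPKM, checked to within 0.01; it is listed as 15, negative for a knockdown at 0, where 1 side is at 0. It was listed as 0 in spite of different FPKM for 1 gene in each replicate (Ano1 in replicate A and Hmga1 in replicate B). The authors' mean FPKM is the mean of the 4 FPKM values, and its lowest value is 1.00, so only genes with a mean of at least 1 FPKM are listed. The authors' p-values reach down to 5e-05, which held for 14 genes in replicate A and 26 in replicate B, and their q-values to 0.0312 and 0.0207. How many genes the authors' q-values were adjusted over is not given in the sources used here. The authors' p under 0.05 held for 4.42% of genes in replicate A and 6.64% in replicate B.

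The sample labels number replicates 1 and 2, whereas the table names them A and B, and nothing states which is which. No value in the table belongs to a single Cd109 hairpin library. The comparisons planned for 6 separate samples were therefore not run, and the authors' deposited comparison within each replicate, with q under 0.05, was used as the main test, as laid down before the data were examined for a table of this kind. Each q compares the libraries of 1 replicate, of which the control is a single library. FPKM x length of low values was checked for whole multiples of the smallest step, to within 0.1 of a step; 21.3% of 141 values in control A and 13.9% of 72 in control B met this, so no read counts could be recovered and the depth is unknown.

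Rows that shared a symbol, 10 in 5 pairs, carried the same replicate B values for both rows and were left out, which left 10711 genes. Symbols turned into dates were found in 15 rows; 13 were restored from their RefSeq accessions and 2 were among the rows left out. Of the 10711 genes, 10635 matched the RefSeq gene table (assembly GRCm38.p6, which is mm10), which also gave coordinates. Fold changes in both replicates were usable for 10680 genes. An exact 0 can be a failed estimate, so such genes are said to be listed at 0.

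The lists of genes, 33 in all, and the rule for named genes were fixed before the data were examined. The rule takes Cd109; the 12 largest rises and 12 largest falls by mean log2 fold change among genes past the threshold, with at least 1 FPKM in the higher group and the same direction, leaving out predicted and small RNA genes; up to 4 members of each list with the smallest p; and Jak1, Stat3, Socs3 and Il6st. For a table with 2 replicates the threshold was read as q under 0.05 in at least 1 replicate with the same direction in both, and the smallest p as the smallest combined p; this reading was set after the layout of the table was seen. It left 54 falls and 6 rises to choose from.

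For each list the members with q under 0.05 in either replicate, whatever their direction in the other, were counted. They were compared with the other genes by Fisher's exact test (two-sided, Benjamini-Hochberg over lists with at least 5 members). The authors' p-values were also adjusted over the list alone. The median log2 fold change of a list was placed among 10000 random lists of the same size drawn from the same 20 bins of mean FPKM. Such a percentile describes these libraries and is not a test over replicates. The combined p is the signed equal-weight sum of the normal scores of the authors' 2 p-values per gene, with Benjamini-Hochberg adjustment. Limma (version 3.58.1 in R 4.3.3) was fitted to log2(FPKM + 1) of the 4 columns for the 10680 genes, with and without a replicate block, using eBayes with a trend, which leaves 1 and 2 residual degrees of freedom; fold changes on that scale understate the change of low genes. Camera used a preset correlation of 0.01 and an estimated one, and fry was run beside it. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 were used.

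GC content and length came from GENCODE transcripts matched by RefSeq accession, for 99.1% of genes with a fold change. Trends of the fold changes with GC content and length, and with the difference between replicates (mean of both B columns minus mean of both A columns, log2), were removed by lowess with a span of 0.3. Simulated data held 200 changed genes among 10680 in a knockdown and control comparison in 2 replicates. On these the combined p recovered 94.7% of changes of 1 and 100% of changes of 2 on the log2 scale. Of its calls 5.16% were unchanged genes (mean of 20 draws). Each simulated p was computed from the same noise that made the data, and not by the authors' test. These shares therefore do not tell how well the combined p works on the authors' p-values. In a single draw limma recovered 89% and 97% with the replicate block and 0% of either without it. Of simulated unchanged lists, 5.5% lay outside the central 95%. These lists were random draws from the same fold changes, so such a share was built in. Lists of genes that change together were not simulated, so the error rate for the fixed lists is not known.
Alternatives were other thresholds, filters, pseudocounts of 1, 0.5 and 0.1, upper quartile scaling, quantile normalization, each replicate alone, the combined p, limma, and the removal of the 2 trends.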

Results

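Messenger RNA of a mouse tumour cell line, 889PF, was sequenced after knockdown of Cd109 with short hairpin RNAs. The line was derived from tumour cells that had disseminated into the pleural fluid, and its source tumour carried Kras G12D and lacked p53. Cd109 encodes a cell surface protein of the alpha-2-macroglobulin and complement family that is known as a co-receptor of TGF-beta. The 6 samples fell into 3 groups of 2 biological replicates: a control hairpin, Cd109 hairpin 1 and Cd109 hairpin 2. The control is named shGFP in the sample titles and shLuciferase in the cell line genotype. The labels name the line 889PF and the table's columns 889DTC, and they were taken as the same line. Expression is given in FPKM for 10711 genes, with 1 control value and 1 value covering both Cd109 hairpins in each of replicates A and B. These values carry no SD, because each control value is a single library and each knockdown value pools the hairpins. The sequencing depth per library is unknown, because low FPKM values did not fall on whole multiples of a read's worth. The comparisons of a single hairpin with the control, of hairpin 2 with hairpin 1, and the overlap between hairpins were not analysed here, because 1 value covers both hairpins.

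The first comparison asked how far the target was reduced. Cd109, on chromosome 9 from 78615546 to 78716260 in mm10 (NM_153098), was listed at 2.47 FPKM in the control and 0.541 FPKM in the knockdown of replicate A in the authors' deposited table, which is 21.9% of the control. In replicate B the authors' deposited table gave 4.69 FPKM in the control and 1.54 FPKM in the knockdown, or 32.9% of the control. The log2 fold changes were -2.19 (p = 0.00055, q = 0.147) and -1.60 (p = 0.00215, q = 0.215) in the authors' deposited table, so Cd109 was lower in both replicates and did not pass q under 0.05 in either. Combining the authors' 2 p-values for each gene gave Cd109 a Benjamini-Hochberg adjusted p of 0.00112.

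**Figure D1:**
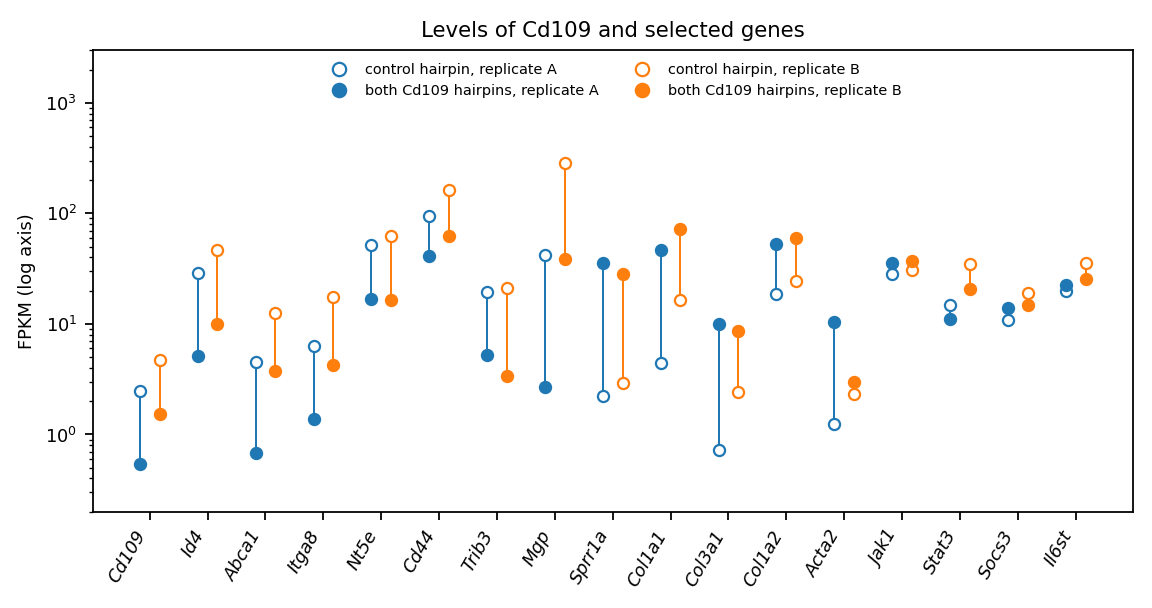
FPKM on a log axis in the control hairpin library (open circles) and in both Cd109 hairpins together (filled circles), for replicate A (blue) and replicate B (orange), with a line joining the values of a replicate. Cd109 lay at 2.47 and 4.69 FPKM in the controls and at 0.541 and 1.54 FPKM in the knockdown, whereas Jak1, Stat3, Socs3 and Il6st moved by less than a factor of 2 in each replicate.

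The main comparison asked which transcripts changed when Cd109 was knocked down. In replicate B lower expression dominated: 52 of the 56 genes past q under 0.05 were lower in the knockdown in the authors' deposited table. In replicate A 13 of the 20 were lower, which is near the share over all genes. Of all genes with a fold change in both replicates, 66.3% were lower in replicate A and 62.1% in replicate B. In both replicates 9 genes passed in the same direction, where independent lists of these sizes would share 0.105 (Fisher's exact test, one-sided p = 2.39e-16). The 7 that fell in both were Id4, Abca1, Itga8, Nt5e, Slc39a10, Igfbp4 and Cd44, and the 2 that rose were Col1a1 and Sprr1a; Slc39a10 and Igfbp4 were named after their values were seen. Of the 67 genes past the threshold in either replicate, 62 had the same direction in both, 55 of them lower and 7 higher. Over all genes with a fold change in both replicates, 70.2% had the same sign. Prss22, Itga2, Ces1g and Tnc passed in 1 replicate with the opposite sign in the other, and Lcn2 was listed at 0 in replicate A; these 5 were named after their values were seen. Adjusting the combined p called 173 genes, 155 lower and 18 higher, which included 54 of the 62.

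Among the falls, Id4, an inhibitor of DNA binding by basic helix-loop-helix factors on chromosome 13 from 48261116 to 48266028, went from 28.7 to 5.09 FPKM in replicate A and from 46.3 to 9.97 FPKM in replicate B of the authors' deposited table. Its q was 0.0312 and 0.0207 in the authors' deposited table. Abca1, the cholesterol efflux transporter, fell by 2.73 and 1.75 on the log2 scale in replicates A and B of the authors' deposited table. The integrin subunit Itga8 fell by 2.20 and 2.05, and Nt5e, which makes extracellular adenosine from AMP, fell by 1.60 and 1.91, again in the authors' deposited table. Mgp, an inhibitor of calcification of the extracellular matrix, had the most negative mean log2 fold change of the genes called with the same direction in both replicates. Its level was 42.4 against 2.66 FPKM in replicate A (q = 0.137) and 286 against 38.7 FPKM in replicate B (q = 0.0207) in the authors' deposited table. Ace, Trib3, Kif21b, Krt20, Il13ra1, Esm1 and Csgalnact1 likewise passed in replicate B alone in the authors' deposited table. Their mean log2 fold changes ran from -2.69 for Ace to -1.85 for Csgalnact1. In controls A and B of that table Ace stood at 0.869 and 8.55 FPKM, Il13ra1 at 1.12 and 11.2 FPKM, and Esm1 at 15.9 and 131 FPKM. Kif21b, Krt20 and Csgalnact1 were also higher in control B, whereas Trib3 stood at 19.5 and 21.3 FPKM. The calls in replicate B rest on that single control library. The genes that passed in replicate B alone were not shown to differ between the replicates, since that difference was not tested.

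The rises were few. Sprr1a, a cornified envelope precursor of squamous epithelium, went from 2.22 to 35.4 FPKM (q = 0.0312) in replicate A and from 2.90 to 28.6 FPKM (q = 0.0483) in replicate B of the authors' deposited table. The fibrillar collagen gene Col1a1 went from 4.39 to 47.1 FPKM and from 16.3 to 72.6 FPKM in the authors' deposited table, a log2 fold change of 3.42 and 2.15. Col3a1 passed in replicate A with a log2 fold change of 3.79 and stood at 1.81 (q = 0.0713) in replicate B of the authors' deposited table. Col1a2 passed in replicate A, from 18.8 to 53.3 FPKM, and was listed at 24.2 and 59.9 FPKM (q = 0.157) in replicate B of the authors' deposited table. Nrep passed in replicate B alone, with log2 fold changes of 2.36 and 3.04 in the authors' deposited table. Acta2, smooth muscle actin, rose in replicate A from 1.25 to 10.4 FPKM and stood at 2.34 and 3.01 FPKM in replicate B of the authors' deposited table. In the 2 controls the collagen genes already differed, with a mean log2 difference of 1.34 between control B and control A over Col1a1, Col1a2 and Col3a1.

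**Figure D2:**
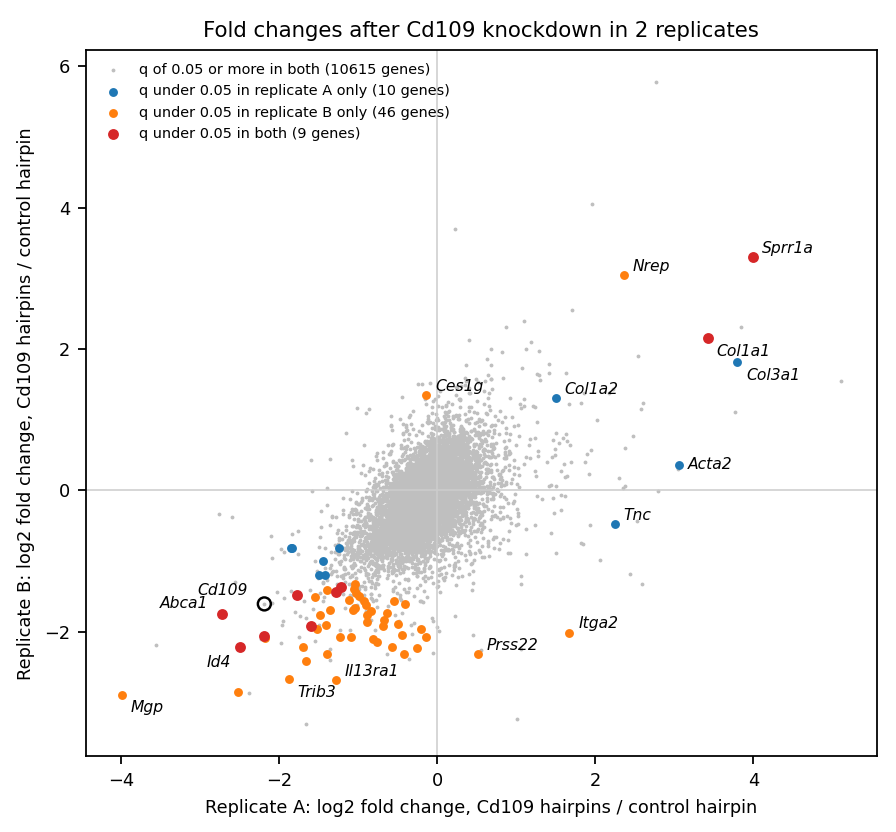
Log2 fold change of both Cd109 hairpins over the control hairpin in replicate A (x axis) and replicate B (y axis), 1 point per gene, for the 10680 genes with a fold change in both. Red points mark the 9 genes with the authors' q under 0.05 in both replicates, blue and orange points those past it in 1 replicate, and the open black circle marks Cd109; Lcn2 and Cxcl3, listed at 0 in the control of replicate A, are not drawn.

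Gene lists fixed before the data were examined were compared with 10000 random lists matched on mean expression. The median log2 fold change of all genes was -0.12 in both replicates, and upper quartile scaling moved it to 0.00 and 0.01. Each list is therefore placed by its percentile, which takes that shift into account. Of the 10680 genes with a fold change in both replicates, 5267 were lower in both and 2232 higher in both. Of 27 lists with at least 5 genes, 5 lay outside the central 95% of random lists on the same side in both replicates: glycolysis and hypoxia, unfolded protein and ATF4, and Jak-Stat components on the low side, and histones and fibroblast markers on the high side. By the limma camera test these 5 passed with a preset correlation of 0.01. Each had an adjusted p = 0.859 with an estimated correlation, at which none of the 27 lists passed. That version has only the 1 residual degree of freedom of the fit, so a list could hardly pass. Histones failed it by camera (adjusted p = 0.000249 with the preset correlation) although their estimated correlation was -0.0909, below the preset one. The camera values with an estimated correlation, here and below, therefore decide nothing for or against a list.

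Glycolysis and hypoxia genes were lower as a group. The list's median log2 fold change was -0.70 in replicate A and -0.81 in replicate B, below every one of the 10000 random lists, and 21 of its 23 members were lower in both. By camera the list had an adjusted p = 0.859 with an estimated correlation. Members past q under 0.05 numbered 3, all lower: Bnip3, a mitochondrial autophagy receptor, in replicate A, and Ndrg1 and P4ha2 in replicate B of the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.00194). Adjusted over the list alone, 8 passed in at least 1 replicate, all lower, and 7 members passed with the combined p over all genes. P4ha2, a collagen prolyl hydroxylase, was named after its value was seen. Pgk1, a glycolytic kinase, was listed at 711 and 345 FPKM in replicate A and at 2199 and 845 FPKM in replicate B of the authors' deposited table, with q of 0.323 and 0.340. Vegfa, the angiogenic factor, had log2 fold changes of -1.24 and -1.04 with q of 0.0964 and 0.372 in the authors' deposited table. The same list also separated the controls: its median was higher by 1.80 on the log2 scale in control B than in control A. With the fold changes' trend on the difference between replicates A and B removed, the medians were -0.39 and -0.12, at percentiles 0 and 3.62, so the list left the low tail in replicate B.

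Unfolded protein and ATF4 genes, which respond to endoplasmic reticulum stress and amino acid shortage, were lower as a group too. Their median log2 fold change was -0.46 in replicate A and -0.88 in replicate B, below every random list, and 20 of 22 members were lower in both. By camera the list had an adjusted p = 0.859 with an estimated correlation. The 2 members past q under 0.05, both lower in replicate B, were the pseudokinase Trib3 and the cystine transporter Slc7a11 (Fisher's exact test, two-sided, adjusted p = 0.0246). Adjusted over the list alone, 9 passed in at least 1 replicate, all lower, and 6 members passed with the combined p over all genes. Trib3 was listed at 19.5 and 5.29 FPKM in replicate A and at 21.3 and 3.35 FPKM in replicate B of the authors' deposited table. Asns, asparagine synthetase, had log2 fold changes of -1.04 and -1.16 (q = 0.350 and 0.221), and Mthfd2 -0.90 and -1.17 (q = 0.562 and 0.222), in the authors' deposited table. With the combined p over all genes the adjusted p was 0.00341 for Asns and 0.00885 for Mthfd2. Between the 2 controls this list's median differed by 0.10 on the log2 scale.

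None of the 24 measured Jak-Stat components passed q under 0.05 in the authors' deposited table or adjusted over the list alone. With the combined p none passed over all genes and 4 passed adjusted over the list alone. As a group their median log2 fold change was -0.32 and -0.44, at percentiles 0.77 and 0.11 of random lists, and 18 of 24 were lower in both replicates. By camera the list had an adjusted p = 0.859 with an estimated correlation. The members with the smallest combined p were Ifnar1, Lifr, Il4ra and Jak3; Lifr, the leukaemia inhibitory factor receptor, stood at 2.41 and 1.13 FPKM in replicate A and at 6.20 and 2.47 FPKM in replicate B of the authors' deposited table (q = 1.00 in A, 0.486 in B). Stat3 had log2 fold changes of -0.42 and -0.75, with q of 1.00 and 0.683 in the authors' deposited table. Jak1 stood at 0.35 and 0.29, Socs3, a feedback inhibitor induced by Stat3, at 0.35 and -0.35, and Il6st, the shared receptor of interleukin-6 cytokines, at 0.18 and -0.49 in the authors' deposited table. Of 27 measured Stat3 targets, Lcn2 alone passed, in replicate B; 6 passed adjusted over the list alone, all lower. The Stat3 target median lay at percentile 63.3 in replicate A and below every random list in replicate B (medians -0.09 and -0.47), and with the trend between replicates removed at percentiles 82.3 and 1.07 (medians 0.06 and -0.15). With the trend between replicates removed the Jak-Stat component medians were -0.11 and -0.09, at percentiles 6.62 and 10.0.

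Lists of adhesion, matrix, mesenchymal and metastatic state genes each held called genes. Of 19 integrin and adhesion genes, Itga6, Cd44 and Itga2 were past q under 0.05 and lower in at least 1 replicate in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.00142), and 5 passed adjusted over the list alone, all lower. Itga2 was lower in replicate B alone, with log2 fold changes of 1.67 (q = 0.947) in replicate A and -2.01 (q = 0.0491) in replicate B of the authors' deposited table. Cd44, the hyaluronan receptor, fell from 95.3 to 41.0 FPKM in replicate A and from 162 to 62.7 FPKM in replicate B of the authors' deposited table. Itga6 had log2 fold changes of -1.12 (q = 0.133) and -1.55 (q = 0.0207) in the authors' deposited table, and its partner Itgb4 -1.35 and -1.18 (q = 0.428 and 0.584). Itga6 and Itgb4 passed with the combined p over all genes (adjusted p = 7.53e-05 and 0.0296). The adhesion medians were -0.26 and -0.60, at percentiles 3.89 and 0; with the trend between replicates removed they were 0.00 and -0.13, at percentiles 43.2 and 5.30. With a pseudocount of 1 they lay at percentiles 1.71 and 0, and with a mean of at least 5 FPKM at 1.01 and 0, so the list was then below the central 95% in both replicates. Of 18 genes tied to the metastatic state in earlier work, which include Cd109 itself, Cd44, Itga2 and Tnc passed (adjusted p = 0.00142 by Fisher's exact test, two-sided; 6 adjusted over the list alone, 5 lower and 1 higher), of which Tnc, a matrix glycoprotein, rose in replicate A and had a log2 fold change of -0.47 in replicate B of the authors' deposited table. Of 18 mesenchymal genes, Cd44 and Tnc passed (Fisher's exact test, two-sided, adjusted p = 0.0213; 3 adjusted over the list alone, 2 lower and 1 higher). Itga2 and Tnc, which count in these Fisher's tests, had opposite signs in the 2 replicates. The tests were not run without them. Of 24 matrix genes, the 3 collagens named above passed (Fisher's exact test, two-sided, adjusted p = 0.00194). Adjusted over the list alone 8 passed, 3 lower and 5 higher, and by camera the list had an adjusted p = 0.859 with an estimated correlation. Of 28 TGF-beta targets these 3, Acta2 and Tgfbi passed (Fisher's exact test, two-sided, adjusted p = 9.77e-06). Tgfbi was lower in replicate B, at a log2 fold change of -1.61 in the authors' deposited table. Adjusted over the list alone 6 TGF-beta targets passed, 2 lower and 4 higher. With the combined p over all genes 3 passed, all higher, and Acta2 and Tgfbi did not (adjusted p = 0.0539 and 0.0520). These lists share members, so their tests are not independent.

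Genes fed back from MAPK signalling included 2 falls among 21, Egr1 in replicate A and Areg in replicate B (Fisher's exact test, two-sided, adjusted p = 0.0246; 6 adjusted over the list alone, 5 lower and 1 higher). By camera the MAPK list had an adjusted p = 0.00751 with the preset correlation of 0.01. With an estimated correlation (0.0667) the adjusted p was 0.859. With the combined p over all genes 5 members passed, all lower, among them Egr1 and Areg (adjusted p = 0.00433 and 0.00775). By limma with a replicate block neither Egr1 nor Areg passed (adjusted p = 0.0501 and 0.0674). Egr1, an immediate early transcription factor, was listed at 82.3 and 22.7 FPKM in replicate A and at 576 and 327 FPKM in replicate B of the authors' deposited table. Areg, an EGF receptor ligand, was listed at 188 and 49.5 FPKM in replicate B, with a log2 fold change of -0.69 (q = 1.00) in replicate A of the authors' deposited table. The MAPK medians were -0.20 and -0.60, at percentiles 8.07 and 0, and with the trend between replicates removed -0.08 and -0.13, at percentiles 9.67 and 3.59. With a mean of at least 5 FPKM they lay at percentiles 1.31 and 0, and with the GC and length trend removed at 1.76 and 0, below the central 95% in both replicates.

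None of the 35 proliferation genes passed q under 0.05. Their median was inside the central 95% of random lists in replicate A, at percentile 3.89 (-0.19), and above every random list in replicate B (0.39). With the trend between replicates removed it was at percentile 0.02 in replicate A and 100 in replicate B, on opposite sides. The helicase subunit genes Mcm5 and Mcm2 had log2 fold changes of 0.26 and 0.14 in replicate A and of 1.05 and 1.12 in replicate B of the authors' deposited table, with q of at least 0.282. The 19 protease and inhibitor genes had medians above every random list in replicate A (0.21) and below every one in replicate B (-0.50), with no member past q under 0.05 and 1 adjusted over the list alone. With the trend between replicates removed their median in replicate B was -0.05, at percentile 23.2. Histone genes, 11 measured, had medians of 0.54 and 0.63, above every random list, with no member past q under 0.05 and none adjusted over the list alone; restricted to genes with a mean of at least 5 FPKM the median of the 5 left was -0.25 in replicate B, at percentile 17.6. Histone genes lie in near-identical copies and mostly lack a poly-A tail, so their FPKM after poly-A selection are uncertain.

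Markers of other cell types were measured beside these groups. Of 12 fibroblast markers fixed in advance 6 were listed, and Col1a1, Col3a1, Col1a2 and Acta2 passed q under 0.05, all higher (Fisher's exact test, two-sided, adjusted p = 5.61e-07; 5 adjusted over the list alone, of which 1, Dcn, was lower). By camera the list had an adjusted p = 0.859 with an estimated correlation. These 4 genes also stand in the TGF-beta target list, and Pdgfrb and Dcn were named after their values were seen. Pdgfrb was listed at 8.65 and 11.1 FPKM in replicate A and at 14.1 and 17.1 FPKM in replicate B of the authors' deposited table, with q of 1.00 in both. Dcn, an abundant fibroblast transcript, was listed at 0 and 0.0452 FPKM in replicate A and at 5.24 and 0.296 FPKM in replicate B of the authors' deposited table (q = 0.208 in B). Markers of leukocytes (4), of the mesothelium (4) and of endothelium (1) were measured, none past q under 0.05, and 0 erythroid markers and 0 mitochondrially encoded genes were listed. The mesothelial markers Krt19 and Igfbp6 passed adjusted over the list alone in replicate A, both lower. Msln of the same list was higher, at 110 and 168 FPKM in replicate A and 97.1 and 127 FPKM in replicate B. Slpi, the last of the 4, was listed at 0.240 and 0.454 FPKM in replicate A, too low to give a direction. In replicate B it stood at 4.62 and 2.52 FPKM (unadjusted p = 0.273 in the authors' test). Cd14 of the leukocyte list stood at 6.97 and 7.41 FPKM in replicate A and at 19.0 and 8.99 FPKM in replicate B of the authors' deposited table.

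**Figure D3:**
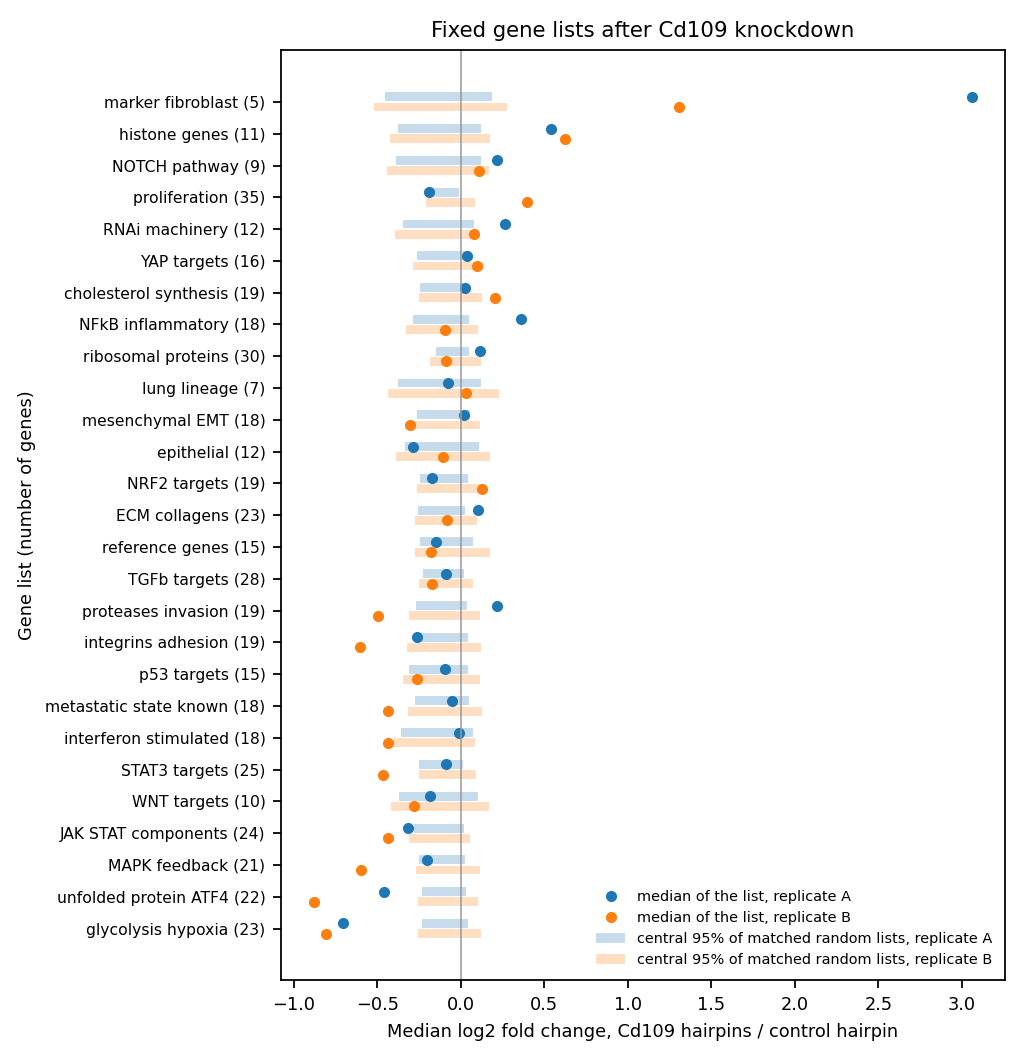
Median log2 fold change of each fixed gene list in replicate A (blue points) and replicate B (orange points), with bars for the central 95% of 10000 random lists matched on mean expression; the number of genes with a fold change stands in brackets. Glycolysis and hypoxia (-0.70 and -0.81) and unfolded protein and ATF4 genes (-0.46 and -0.88) lay left of their bars in both replicates, fibroblast markers (3.06 and 1.31) right of theirs, and protease genes on opposite sides.

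The remaining lists stayed inside the central 95% of random lists in at least 1 replicate. Above it in replicate A and inside it in replicate B were NF-kB inflammatory genes (median 0.36), matrix genes (0.11), ribosomal proteins (0.12), RNA interference machinery (0.27) and the Notch pathway (0.22). In replicate B, and inside it in replicate A, interferon-stimulated genes (-0.44), mesenchymal genes (-0.31) and genes of the metastatic state (-0.43) lay below it and cholesterol synthesis genes (0.21) above it. Epithelial, lung lineage, p53 target, NRF2 target, Wnt target, YAP target, TGF-beta target and reference genes lay inside it in both replicates. With the trend between replicates removed, interferon-stimulated (percentile 40.6), mesenchymal (90.1) and cholesterol synthesis genes (median -0.05) were inside it in replicate B, and metastatic state genes stayed below it (0.47). Under that setting NF-kB, matrix and YAP target genes lay above it in both replicates, at percentiles of at least 99.9. There Notch genes were inside it in both, interferon-stimulated (98.7) and mesenchymal genes (97.6) above it in replicate A, and in replicate B TGF-beta targets (99.9) above it and p53 targets (2.41) below it. In these lists, beyond the genes named above, Slc7a11 of the NRF2 targets, Nt5e of the YAP targets and Lcn2 of the NF-kB genes were past q under 0.05. The fold changes of replicates A and B correlated across 10680 genes at Pearson's r = 0.542, and genes are not independent replicates. Control A and control B differed by more than either differed from its knockdown. The SDs of the log2 difference across genes were 0.756 between the controls, 0.422 within replicate A and 0.478 within replicate B. The SD was 0.879 between knockdown A and control B, 0.585 between control A and knockdown B, and 0.570 between the knockdowns. Control B thus lay further from both columns of replicate A than knockdown B did.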

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

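The combined p, limma, camera and fry, the 2 trend removals and the keeping of rows that share a symbol were chosen after the data were seen; the other settings were planned. With q under 0.01 the counts of genes were 0 in replicate A, 0 in replicate B and 0 in both, because the lowest q listed was 0.0312 and 0.0207; at an unadjusted p under 0.05 the authors' deposited table holds 473 and 711 genes, 213 of them in both with the same direction. With q under 0.1 the count in both replicates was 15, against 9. Either replicate alone gave 20 to 56 genes, against 9 for both. The combined p called 173 genes and limma with a replicate block 334, each with all 9 among them. Of the 62 genes called in either replicate with the same direction in both, the combined p held 54 and limma with a replicate block 40. Limma with no replicate block called 0 (413 at an unadjusted p under 0.05, and 0% of simulated changes recovered). The labels do not say what the replicate numbers share; the B minus A differences of the controls and of the knockdowns correlate across genes at r = 0.822. The limma count with a replicate block has 1 residual degree of freedom and moved to 65 with rows listed at 0 kept, 59 with eBayes without a trend and 605 with a pseudocount of 0.1; the cause was not tested. For Cd109 the log2 fold change was -1.90 on average (-2.19 to -1.60 with either replicate left out), -1.17 with a pseudocount of 1, -1.43 with 0.5 and -1.45 with the trend between replicates removed; adding a pseudocount pulls low genes toward 0. Cd109 passed with the combined p (-1.90, adjusted p = 0.00112) and with limma and a replicate block (-1.17, adjusted p = 0.0389; without a trend 0.0423, and with a pseudocount of 0.1 a log2 fold change of -1.77 and adjusted p = 0.0255), and did not with rows listed at 0 kept (0.0513) or with no replicate block (0.983).

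The lists outside the central 95% on the same side in both replicates numbered 5, and 8 with the GC and length trend removed; either replicate alone gave 11 to 14. Camera on the limma fit with a replicate block called 11 lists with the preset correlation and 0 with an estimated one, and fry called 0. With 1 residual degree of freedom the last 2 could hardly call a list, so their counts decide nothing. Over the settings of the list medians, with the GC and length trend and each replicate alone included, the call was kept in 294 of 323 cases. It was gained in 26 and lost in 3. In 2 of these settings, with 27 cases each, no call could change. Upper quartile scaling shifts every fold change by a constant, and the filter of at least 1 FPKM in the higher group kept all 10680 genes. Glycolysis and hypoxia and Jak-Stat components ceased to be called with the trend between replicates removed, and histones with a mean of at least 5 FPKM. With the trend between replicates removed NF-kB, matrix and YAP target genes were called in addition; so were adhesion genes with a pseudocount of 1, adhesion and MAPK genes with a mean of at least 5 FPKM, MAPK genes with the GC and length trend removed, and cholesterol synthesis genes and RNA interference machinery with that trend removed or with quantile normalization. No call on the mean of both replicates reversed its sign, but within replicate B some medians did. The histone median went from 0.63 to -0.25 with a mean of at least 5 FPKM. With the trend between replicates removed, the mesenchymal (from -0.31 to 0.11) and cholesterol (from 0.21 to -0.05) medians changed sign. So did medians that had been inside the central 95%, such as those of NF-kB (-0.09 before) and matrix genes (-0.08 before). Limma with a replicate block called the Jak-Stat genes Ifnar1 (adjusted p = 0.0439) and Jak3 (0.0447), Asns (0.0317) and Mthfd2 (0.0389). Requiring a fold change of at least 2 or at least 1 FPKM in the higher group removed none of the called genes. The second filter could remove none, because only genes with a mean of at least 1 FPKM are listed. Of the named genes past the threshold, 14 lost it without replicate B and 5 without replicate A. The settings planned for 6 separate samples (a single hairpin against the control, the hairpins against each other, their overlap, and leaving out a single hairpin library) were not run because 1 value covers both hairpins, and genes under a mean of 1 FPKM were not used here. Without counts, the precision that depth gives is unknown.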

Other observations

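The tests with a trend removed were chosen after the data were seen, and those of glycolysis and hypoxia genes within each replicate and of the fibroblast markers after the result each of them measures. The control libraries of replicates A and B differed in groups of genes without any knockdown, as 1 library each and so without a test. Control B stood higher than control A by a median of 1.81 (log2) for NF-kB inflammatory genes, 1.80 for glycolysis and hypoxia, 1.43 for interferon-stimulated genes and 1.05 for MAPK feedback genes, each above every one of 10000 matched random lists. Proliferation genes (-0.97) and cholesterol synthesis genes (-0.78) stood lower, below every random list. Across 10680 genes, which are not independent replicates, the fold changes of the knockdown correlated with this difference of the controls at Pearson's r = -0.0360 in replicate A and -0.633 in replicate B. Each control enters both of the values correlated, which by itself pulls r up in replicate A and down in replicate B. Against the difference of the means of both columns, from which the trend between replicates was taken, r was -0.171 and -0.559. Lcn2, an acute phase protein, was listed at 0 in both columns of replicate A and at 101 and 9.46 FPKM in replicate B of the authors' deposited table. Further genes picked after their values were seen are Sprr2k, at 1.94 and 13.2 FPKM in replicate A and 0.587 and 32.1 FPKM in replicate B of the authors' deposited table, and the synaptic vesicle gene Syp, at 0.540 and 2.09 FPKM and at 0.177 and 2.92 FPKM; neither passed the authors' q, and both passed with the combined p (adjusted p = 0.0114 and 0.0151).

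Glycolysis and hypoxia genes were lower in both replicates (medians -0.70 and -0.81). A candidate explanation is a state of the cultures, such as density or oxygen, that also differs between replicates A and B. With the trend on that difference removed, the list lay at percentile 0 in replicate A, with a median of -0.39, so that trend cannot be the whole explanation there. In replicate B the median went to -0.12 and the list to percentile 3.62, inside the central 95%, so in that replicate the fall may be part of the same state; the call ended because the median moved and not because the random lists spread, which ran from -0.26 to 0.12 before and from -0.13 to 0.15 after. Removal of a GC and length trend left the list at percentile 0 in both replicates, which argues against that explanation, and an effect of the knockdown on the culture state itself stays open.

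Unfolded protein and ATF4 genes were lower in both replicates (medians -0.46 and -0.88). The list's median B minus A difference was 0.10 in the controls and -0.37 in the knockdowns. Removing the trend between replicates could therefore take little of the fall away. That trend did not account for the fall: the list stayed at percentile 0 in both with the trend removed (medians -0.28 and -0.73). GC content and length did not either, with percentile 0 in both. A fall of the ATF4 programme with Cd109 knockdown is a hypothesis that these tests leave standing. A difference in nutrient supply between the control and the knockdown dishes within each replicate could give the same pattern and was not tested.

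Col1a1, Col1a2 and Col3a1 were higher in both replicates (mean log2 fold change 2.91 and 1.76). Fibroblasts mixed into the knockdown cultures would bring their other transcripts as well. Of the 3 other measured fibroblast markers, 2 gained at least 10% of the FPKM that Col3a1 gained in both replicates. They were Pdgfrb with 26.1% and 49.4%, although its q was 1.00 in both in the authors' deposited table, and Acta2 with 98.5% and 10.95%. The gain of Acta2 in replicate B, from 2.34 to 3.01 FPKM, did not pass in the authors' test (unadjusted p = 0.546). Dcn gained 0.485% in replicate A and was lower in the knockdown in replicate B. Fibroblasts and a rise in the tumour cells cannot be told apart, because these markers differ and are few. The trend between replicates predicted a change of -8.59% of the mean rise in replicate A and -25.9% in replicate B, that is a fall, which argues against the culture state as the trend measures it. Whether each hairpin gives the rise was not analysed here, so an off-target effect of 1 hairpin stays open.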
